A study of Mus musculus with 10 samples.

How the data were processed

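RNA-seq was done on beta cells sorted from islets of male NOD mice, 5 libraries from untreated islets and 5 from islets exposed to LPS at 50 ng/ml for 48 hours. Groups and replicate numbers came from the sample titles. The values analysed are raw counts per Ensembl gene identifier, 1 table per library as deposited, with whole numbers that sum to a different total in each library. FastQC, Trimmomatic, STAR, SAMtools, HTSeq and DESeq2 and the mouse build GRCm39 are named, per the submitters' processing notes. Versions and parameters of these tools, the annotation release, the library kit and the use of strand in counting are not given in the sources used here. Counts of a gene can therefore include reads from an overlapping or antisense gene, and reads from the NOD strain were counted against a reference of another strain.

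Each table ends with totals that name no gene, which were left out of library sizes and tests. Relative to all reads in the tables, reads outside genes made up 12.2 ± 1.08% in untreated and 11.0 ± 1.36% in LPS libraries (SD, n = 5 each; exact permutation p = 0.167), ambiguous reads 1.43 ± 0.0352% and 1.52 ± 0.0772% (exact p = 0.0635). Reads that aligned to more than 1 place made up 5.50 ± 0.467% and 5.44 ± 0.547% (exact p = 0.786). Totals assigned to genes ran from 18465200 to 27379900. Of 56748 identifiers, 52073 matched a symbol and 4675 did not, and 24717 had 0 counts in all libraries. For a gene with 0 counts over a group, the upper limit was set at 3 counts. This was 0.0246 CPM for the summed untreated and 0.0269 CPM for the summed LPS libraries. Such limits cover counting error only, since reads are not known to be independent molecules. Every pair of libraries differed by more than sampling noise, with a chi-square per gene of at least 5.71 within groups, so each library was counted as 1 replicate.

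Counts were analysed in R 4.3.3. Genes were kept with edgeR 4.0.16 (filterByExpr, minimum count 10, minimum total count 15), scaled by TMM and tested by the quasi-likelihood F test with no covariate, and p-values were adjusted by Benjamini-Hochberg over the 15942 genes tested. A gene was called at an adjusted p under 0.05. Standard errors are on the log2 scale from the fitted fold change and its test statistic. The labels give the groups no replicate number in common, so this fit has no block. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), which compares a list with all other genes, adjusted over 23 lists and, separately, over 9 marker lists. With a correlation estimated from the residuals, the calls of interferon-stimulated genes, interferon-inducible GTPases, MHC class I, chemokines, cytokines, NF-kB targets, the unfolded protein response and T cell ligands held. Fry, which asks whether the genes of a list move on balance in one direction and does not compare them with other genes, was an alternative. Library composition and marker list means were compared by two-sided exact permutation tests over all arrangements of the libraries, for which the smallest p is 0.00794. Correlations across the 10 libraries used 100000 permutations. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

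The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The pathway lists were interferon-stimulated genes, interferon-inducible GTPases and IFN-gamma-type targets, MHC class I, MHC class II, chemokines, cytokines, NF-kB targets, TLR4 signalling, interferon ligands with receptors and JAK-STAT, nucleic acid sensing, beta cell identity and secretory granule and exocytosis. The others were dedifferentiation and disallowed genes, unfolded protein response, cell death, T cell ligands and checkpoints, oxidative phosphorylation, glycolysis, hypoxia, cholesterol synthesis, antioxidant response, cell cycle and immediate early genes. Marker lists covered macrophages, lymphocytes, alpha, delta, pancreatic polypeptide, acinar, ductal, endothelial and mesenchymal cells. Some genes stand in more than 1 list, such as Icam1, Sod2, Ier3, H2-T23 and Pdx1. Named genes were the 10 with the largest fold change in each direction among called genes with a mean CPM of at least 1 and separated groups (no predicted genes, pseudogenes or genes without a symbol) and 21 genes fixed by name. Also named were up to 3 called members of each list with the smallest adjusted p or, if none was called, its 2 most abundant members, and the 2 most abundant members of each marker list. Genes named beyond that rule are marked as such. Some genes that the rule picks stayed in all fits and lists but are not reported here.

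Other settings fixed in advance were DESeq2 size factors and upper-quartile factors within edgeR, no filter on low counts, a filter at 1 CPM in 5 libraries, DESeq2 1.42.0, limma-voom with and without sample quality weights, library sizes without the 20 most abundant genes, and libraries thinned to the shallowest. So were 1 surrogate variable (sva 3.50.0), the acinar or macrophage list mean as a covariate, and leaving out each library. For lists they were fry, the estimated correlation, a prior count of 0.5 and leaving out members shared with marker lists. Alternatives added after the data were seen were the second principal component, the endothelial or alpha cell list mean, or the share of ENSMUSG00000119584 as covariates, leaving out the 4 libraries at the ends of that component, and a block for the order of the title numbers within each group. GC content and transcript length came from GENCODE M21 transcripts, an annotation of an older mouse build, and were found for 97.9% of tested genes.

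The gene and list tests were tested on simulated counts of the LPS comparison, with the real genes, means and library sizes and 200 genes changed. EdgeR, run on 15690 genes, called 59% of genes changed 1.5-fold and 78% of those changed 2-fold, with 7 false calls among 144. DESeq2, run on 15942 genes, called 68% and 84% with 23 false among 175, and limma-voom, on 15690 genes, 57% and 76% with 8 false among 141. Camera, run on 23 lists, called the 1 list that was moved, the unfolded protein response, and 0 of the other lists counted. MHC class I and immediate early genes, which share members with the moved list, were left out of that count. Each gene was simulated independently, so the effect of correlation between genes on camera was not tested.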

Results

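The data were RNA-seq gene counts of beta cells sorted by flow cytometry from pancreatic islets of male NOD mice aged 6 to 8 weeks. NOD is an inbred strain that develops autoimmune diabetes spontaneously. Intact islets were kept in culture for 48 hours either without addition (untreated, n = 5 libraries, numbered 1 to 5) or with 50 ng/ml of lipopolysaccharide (LPS, n = 5 libraries, numbered 6 to 10), and were dispersed and sorted afterwards. LPS is a bacterial cell wall component sensed through Toll-like receptor 4. The labels call the libraries independent samples but do not name the animals behind each. Total counts assigned to genes ran from 18465200 in LPS 9 to 27379900 in LPS 7, with means of 24429300 ± 1160670 (SD) in untreated and 22344300 ± 3483090 in LPS libraries. This difference was within the spread between libraries (two-sided exact permutation test, p = 0.246), but not without LPS 7 (p = 0.0317). Of 56748 gene identifiers, 15942 passed the filter on low counts and were tested.

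The comparison of LPS with untreated asked which genes of the sorted cells differed after exposure of the islets to LPS, with the chemokine Cxcl10 named in the series title. Interferon-stimulated genes, NF-kB target genes and genes of MHC class I antigen presentation rose in the LPS libraries, and a small set of beta cell genes fell. In total 601 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 453 higher and 148 lower in LPS. The increases were larger: 164 of the higher genes differed at least 2-fold and 8 of the lower ones, and the median size of the log2 fold change was 0.73 among higher and 0.42 among lower genes. Every library of one group lay above every library of the other for 910 genes, against a chance share of 0.794% of genes, and for 535 of the 601 called genes. DESeq2 called 949 genes, limma-voom with sample quality weights 994 and edgeR with 1 surrogate variable 1335, or 2450 (1336 higher, 1114 lower) with a block for the order of the title numbers, which the labels do not give. Among the genes named here as called, Cd14, Il1rn, Pfkp, Slc7a11, Cd68, Ppy, Kdr, ENSMUSG00000119584 and, further below, Pigr, Gria2, Ngfr and Lars2 had overlapping groups.

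Genes were ranked among those called, separated, with a symbol and with a mean of at least 1 CPM, without predicted genes and pseudogenes. The largest increase was that of Duox2 (log2 fold change 5.59 ± 0.97 SE, edgeR adjusted p = 0.00448), a hydrogen peroxide-producing oxidase. Slc6a14 (4.95), an amino acid transporter, and Ltf (4.62), which encodes the iron-binding protein lactoferrin, came next. They were followed by the protease inhibitor gene Slpi (4.55), the metalloreductase gene Steap4 (4.39), Lrg1 (4.20), Lcn2 (3.96), Vnn3 (3.82), the complement factor B gene Cfb (3.76) and Crispld2 (3.69). Lcn2, which encodes a siderophore-binding lipocalin, was the most abundant of these and went from 51.0 ± 24.0 CPM (normalised counts relative to the library total; SD, n = 5) to 793 ± 283 CPM. The other 9 stayed under 32 CPM on average in both groups. The largest decreases in the same ranking were smaller and ran from -1.05 for Plk5 to -0.86 for Slc2a2, the gene of the glucose transporter GLUT2. In between lay Csgalnact1 (1.99-fold lower), the potassium channel gene Kcnj3 (-0.94), Akap6 (-0.93), the cholesterol hydroxylase gene Cyp46a1 (-0.91), the calcium-binding protein gene Calb1 (-0.89), Dpp10 (-0.88), Cilp (-0.87) and Vwa5b1 (-0.87). When libraries were left out in turn, the calls of Plk5 and Cilp were lost in 8 of the 10 fits, those of Csgalnact1 and Cyp46a1 in 7 and that of Kcnj3 in 6, with adjusted p up to 0.127. The 10 increases kept their calls in all 10 leave-one-out fits. Their log2 fold changes ran from 4.73 to 6.36 for Duox2, from 4.65 to 6.35 for Slc6a14 and from 4.35 to 5.58 for Ltf, so that their order is not fixed. With covariates added after the data were seen, Duox2 was not called with the endothelial list mean (edgeR adjusted p = 0.143). Neither Duox2 (0.314) nor Cfb (0.0560) was called with the share of ENSMUSG00000119584. Of the decreases in this ranking, only Slc2a2 kept its call with the endothelial covariate.

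**Figure D1:**
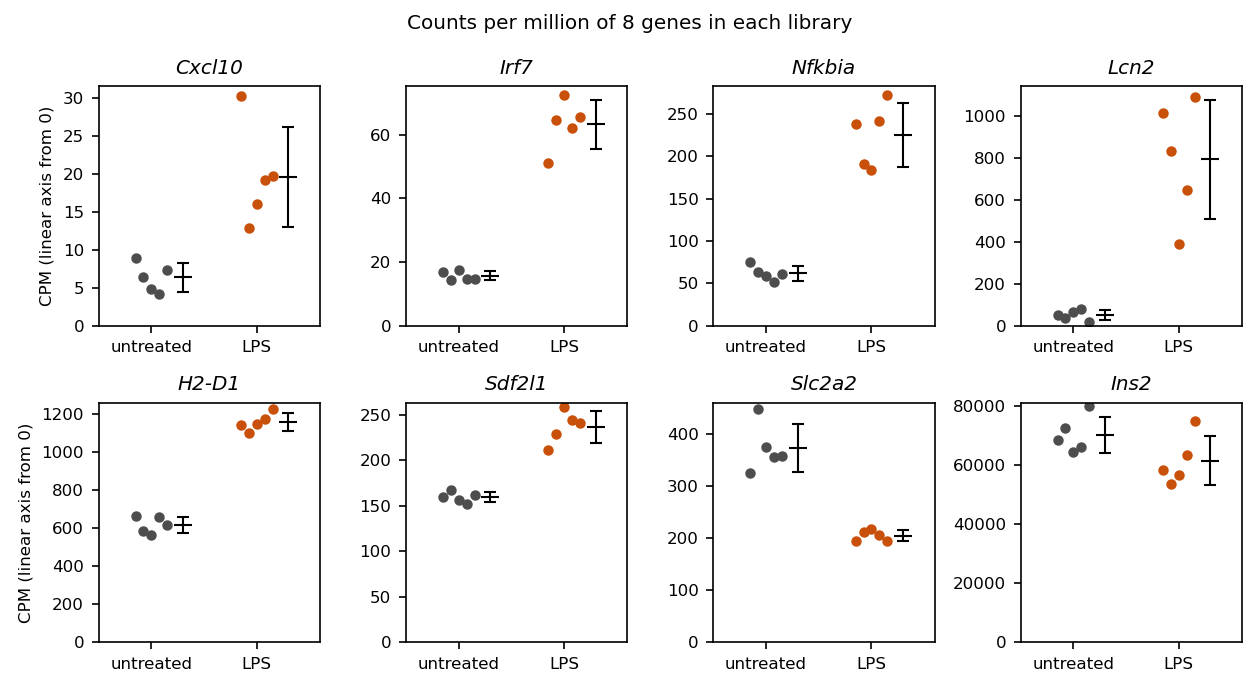
Normalised counts (CPM, linear axes from 0) of 8 genes in the 5 untreated and 5 LPS libraries; each dot is a library, and the dash with bars is the group mean ± SD. Cxcl10, Irf7, Nfkbia, Lcn2, H2-D1 and Sdf2l1 lie higher and Slc2a2 lower in all LPS libraries, while the groups overlap for Ins2 (log2 fold change -0.19, edgeR adjusted p = 0.432).

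Chemokine genes were low in untreated cells, and 4 of the 9 measured rose with LPS. Cxcl10 (ENSMUSG00000034855) encodes an interferon-inducible ligand of CXCR3, a chemokine receptor on T cells. It went from 6.36 ± 1.90 to 19.6 ± 6.53 CPM (SD, n = 5 each), a log2 fold change of 1.62 ± 0.24 (SE; edgeR adjusted p = 0.00123). Ccl28 rose from 13.5 to 46.4 CPM (log2 fold change 1.78), the neutrophil attractant gene Cxcl1 from 1.00 to 8.75 CPM (3.13) and the monocyte attractant gene Ccl2 from 0.170 to 1.92 CPM (3.44; 3.02 to 4.15 with single libraries left out). The list passed camera, a test of a list against all other genes (adjusted p = 9.08e-06; 0.0205 with an estimated correlation), with 5 members past the threshold when adjusted over the list alone. Cxcl9, Ccl5 and Ccl20 were too low to be tested, with 3, 9 and 2 counts summed over the untreated and 1, 22 and 13 over the LPS libraries. Of 13 measured cytokine genes, 5 rose, among them Csf1 (0.76), the growth factor of macrophages, Tnf (2.68) and Lif (1.75), with Tnfsf10 and Il1rn, which the naming rule did not pick, as the others (camera adjusted p = 0.00102; 5 higher and 1 lower adjusted over the list alone). With the share of an abundant unnamed gene as a covariate, a setting chosen after the data were seen, Cxcl10 had a log2 fold change of 1.40 ± 0.39 (SE) and was no longer called (adjusted p = 0.161; 4.94e-10 to 0.00590 over the planned settings). Lif was not called without untreated 3 (adjusted p = 0.0520), and 3 cytokine genes were called without LPS 7 or LPS 9.

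Interferon-stimulated genes rose as a group: 35 of 44 measured members were called higher, none lower, and 38 were higher when adjusted over the list alone (camera adjusted p = 1.56e-52; 2.34e-04 with an estimated correlation). Irf7, a transcription factor that amplifies type I interferon production, rose 4.02-fold from 15.7 ± 1.44 to 63.2 ± 7.72 CPM (SD, n = 5; edgeR adjusted p = 2.89e-07). Oas2 (log2 fold change 2.24) and Oasl2 (1.64), of the family of antiviral oligoadenylate synthetases, rose as well. Among interferon-inducible GTPases and related targets, 10 of 18 rose (13 adjusted over the list alone), led by Gbp3 (2.14), Gbp5 (2.37) and Gbp9 (1.01), with a camera adjusted p of 7.00e-16 and of 0.0286 with an estimated correlation. Reads of the Gbp genes and of the Oas1, Ifit3 and Ifit3b copies may have been split between near-identical sequences, so their single values are uncertain.

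Transcripts of type I and II interferons themselves were at or near 0. Ifnb1, Ifna1, Ifna4, Ifna5 and Ifng had 0 counts in all 10 libraries, which allows up to 0.0246 CPM over the untreated and 0.0269 CPM over the LPS libraries (3 counts over each group, counting error only). Of 11 measured genes of interferon ligands, receptors and JAK-STAT signalling, 2 rose: Ifngr2 (log2 fold change 1.04) and Ifnar2 (0.47, edgeR adjusted p = 0.0186), both interferon receptor chains. Their partner chains did not pass, at 40.5 ± 1.94 and 41.0 ± 3.00 CPM (SD, n = 5) for Ifnar1 and at 0.31 for Ifngr1 (adjusted p = 0.110; called with the surrogate variable, adjusted p = 0.0383, and with the macrophage list mean as a covariate, 0.0453). The list as a whole was not called (camera adjusted p = 0.166; 3 higher and 1 lower adjusted over the list alone). Of 6 measured genes of nucleic acid sensing, Ifi203 (2.82) and the RNA-editing enzyme gene Adar (0.26) rose (2 adjusted over the list alone; camera adjusted p = 0.0142, adjusted p = 0.177 with an estimated correlation). Ifnar2 was not called without untreated 4 (adjusted p = 0.0572) or LPS 7 (0.0603), and Adar was lost in 6 of the 10 leave-one-out fits (adjusted p up to 0.0797). The sign of the small Ifnar1 value changed in some fits.

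MHC class I antigen presentation rose at high expression, with 16 of 23 measured members called and 21 when adjusted over the list alone (camera adjusted p = 9.69e-28; 0.00111 with an estimated correlation). H2-D1 went from 617 ± 44.0 to 1158 ± 46.2 CPM (SD, n = 5), H2-K1 from 202 ± 22.8 to 440 ± 73.5 and the light chain gene B2m from 147 ± 31.5 to 395 ± 33.6, log2 fold changes of 0.91, 1.12 and 1.43 (edgeR adjusted p at most 6.34e-05). The class I heavy chain genes are near-identical copies and the NOD haplotype differs from the reference strain, so that the split of reads between single H2 genes is uncertain. MHC class II genes were low, and none of 5 measured members passed in edgeR, DESeq2 or limma-voom, when adjusted over the list alone or, in edgeR, at an unadjusted p of 0.05. Its most abundant members were H2-DMa at 6.50 ± 1.56 and 6.75 ± 0.923 CPM and Cd74 at 4.08 ± 2.65 and 5.47 ± 1.36 CPM, with a camera adjusted p of 0.0846 for the list. That list passed without untreated 3 or untreated 4, with adjusted p = 0.0454 and 4.62e-04. Of 9 measured ligands and checkpoints of T cells, 4 rose (5 adjusted over the list alone): Lgals9 (log2 fold change 2.33), the adhesion molecule gene Icam1 (3.02), H2-T23 (0.79) and Cd47 (0.35), the last one outside the naming rule (camera adjusted p = 2.96e-06; 0.00511 with an estimated correlation). Cd274, which encodes PD-L1 and was likewise named after its value was seen, did not pass (0.25).

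NF-kB target genes rose as well, 25 of 33 measured and 29 when adjusted over the list alone, with none lower (camera adjusted p = 6.16e-37; 0.00916 with an estimated correlation). The NF-kB inhibitor gene Nfkbia went from 62.3 ± 8.84 to 225 ± 37.2 CPM (SD, n = 5; log2 fold change 1.85), the RNase gene Zc3h12a rose by 2.54 and the co-activator gene Bcl3 by 1.20 on the log2 scale (edgeR adjusted p at most 5.41e-06). Nos2, the inducible nitric oxide synthase gene, rose from 0.0651 ± 0.106 to 1.53 ± 0.805 CPM (4.43, adjusted p = 0.00261), a level of few counts per library (4.12 to 5.88 with single libraries left out). The LPS receptor gene Tlr4 was low, at 0.685 ± 0.417 and 0.734 ± 0.238 CPM, and was not called (0.09 ± 0.41, adjusted p = 0.950; its sign changed in some fits), nor was the co-receptor gene Ly96 (0.39, adjusted p = 0.205). Of 25 measured members of the TLR4 signalling list, Cd14 (0.93, adjusted p = 0.0313) and the adaptor gene Myd88 (0.35, adjusted p = 0.0285) rose, the same number as adjusted over the list alone. The list passed camera (adjusted p = 0.0337) but not with an estimated correlation (adjusted p = 0.267), nor without untreated 5, LPS 6 or LPS 7 (adjusted p up to 0.190). Leaving out single libraries ended the call of Myd88 in 8 and of Cd14 in 6 of the 10 fits (adjusted p up to 0.0886).

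Of 30 beta cell identity genes, 5 fell and none rose, with the insulin genes not among them. Slc2a2 fell from 372 ± 45.7 to 205 ± 10.2 CPM (SD, n = 5; log2 fold change -0.86 ± 0.08 SE, edgeR adjusted p = 4.30e-05), the granule zinc transporter gene Slc30a8 from 523 ± 24.6 to 347 ± 17.9 (-0.59) and the cation channel gene Trpm5 from 198 ± 17.4 to 123 ± 18.8 (-0.69). The other 2, chosen after their values were seen, were Ucn3 (-0.64), a marker of mature beta cells, and the incretin receptor gene Glp1r (-0.41). Ins2 stood at 70376 ± 6166 and 61582 ± 8370 CPM and Ins1 at 36482 ± 2465 and 33957 ± 4290, and neither passed (-0.19 and -0.10; adjusted p = 0.432 and 0.694). The transcription factor genes Mafa (-0.23, adjusted p = 0.254) and Pdx1 (-0.19, adjusted p = 0.307) did not pass either. With the surrogate variable 10 beta cell genes were called lower, Pdx1 (adjusted p = 0.0323) among them, and 1 higher. With a block for the order of the title numbers, chosen after the results were seen and not given by the labels, 13 were called lower, among them Ins2 (adjusted p = 0.0199), Mafa (0.0236) and Pdx1 (0.0326). As a list the 30 genes were lower (median -0.10, camera adjusted p = 9.08e-06), with adjusted p = 0.0655 with an estimated correlation, and 7 were lower and 1 higher when adjusted over the list alone. Markers of alpha, delta and pancreatic polypeptide cells also had medians under 0, while ductal markers had a median of 0.29, as given below.

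Genes of secretory granules and exocytosis went both ways. Of 22 measured, the granin gene Chgb (log2 fold change 0.74) and the granule membrane protein gene Ptprn (0.29) rose and Sytl4 (-0.30), an effector of granule docking, fell, with 4 higher and 2 lower when adjusted over the list alone. The list was not called (camera adjusted p = 0.781), and its median of -0.03 and mean of 0.04 differed in sign. Chgb reached 5034 ± 358 CPM from 3014 ± 321 (SD, n = 5; edgeR adjusted p = 2.10e-04), the largest gain in CPM among the called genes named here. Of 12 genes of dedifferentiation or normally silent in beta cells, Igfbp4, a binding protein of insulin-like growth factors, rose (1.38; 2 adjusted over the list alone; camera adjusted p = 0.166). Ptprn was not called without untreated 3, untreated 4 or LPS 7 (adjusted p = 0.0610, 0.0540 and 0.0529).

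The unfolded protein response list shifted by small steps in one direction, with 8 of 25 members higher, none lower and 13 higher when adjusted over the list alone (median 0.25, camera adjusted p = 1.14e-11; 0.00511 with an estimated correlation). The endoplasmic reticulum genes Sdf2l1 (159 ± 5.67 to 237 ± 17.5 CPM, SD, n = 5; log2 fold change 0.57), Creld2 (0.49) and Edem1 (0.44) led it. Of 27 measured cell death genes 5 rose, among them the inflammatory caspase genes Casp4 (3.05) and Casp1 (2.00) and the TNF receptor gene Tnfrsf1a (0.53), and 8 were higher and 1 lower when adjusted over the list alone. The other 2, named after their values were seen, were Bcl2l1 (0.36), which has an anti-apoptotic product, and Bak1 (0.29), which has a pro-apoptotic one. The cell death list passed camera (adjusted p = 1.77e-04) but not with an estimated correlation (adjusted p = 0.0572). Of 22 antioxidant genes, Txn1 (0.40), Sod2 (0.40), Gsr (0.32) and the cystine transporter gene Slc7a11 (0.85), again outside the rule, rose (6 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00390, adjusted p = 0.267 with an estimated correlation). Gsr was not called without untreated 3 (adjusted p = 0.0692) or LPS 7 (0.0527), and 2 to 5 antioxidant genes were called with single libraries left out.

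Lists of metabolism and growth held few or no called genes. A block for the order of the title numbers, added after the data were seen, called more genes of oxidative phosphorylation, cholesterol synthesis and cell cycle, as given below. None of 34 oxidative phosphorylation genes and none of 20 cholesterol synthesis genes passed in edgeR, DESeq2 or limma-voom or when adjusted over the list alone, with 5 and 3 at an unadjusted p under 0.05 in edgeR. With quality weights limma-voom called 1 gene of oxidative phosphorylation, and edgeR with the surrogate variable called 1 there and 5 of cholesterol synthesis. The shifts of these lists in camera (medians 0.07 and 0.17; adjusted p = 0.00527 and 0.00387) were lost with an estimated correlation (adjusted p = 0.421 and 0.427). The ATP synthase genes Atp5b (517 ± 12.0 and 531 ± 9.05 CPM; SD, n = 5) and Atp5a1 (472 ± 19.7 and 465 ± 22.5) were the most abundant of oxidative phosphorylation, and the sign for Atp5a1 changed in some fits. In glycolysis only Pfkp of 16 rose (log2 fold change 0.49, edgeR adjusted p = 0.0457; 1 adjusted over the list alone), with a camera adjusted p of 0.00274 and an adjusted p of 0.396 with an estimated correlation. The hypoxia list was not called (camera adjusted p = 0.0917), although the collagen prolyl hydroxylase genes P4ha1 (0.53) and P4ha2 (0.24) rose, 2 of 14 members and 2 adjusted over the list alone. None of 22 cell cycle genes passed in edgeR, DESeq2 or limma-voom or adjusted over the list alone, with 1 at an unadjusted p under 0.05 in edgeR (camera adjusted p = 0.266). The abundant members Ccnd2 (-0.15) and Cdk4 (0.05, with a sign that varied between fits) were close to 0. Of 23 immediate early genes that dispersal of tissue can induce, Ier3 (1.10) and Zfp36 (0.42) rose, 2 also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.166). Pfkp and P4ha2 lost their calls in 8 and 7 of the 10 leave-one-out fits (adjusted p up to 0.131), and Zfp36 without untreated 3 (0.0562). Of the list calls, oxidative phosphorylation was lost without LPS 10 (adjusted p = 0.112) and cholesterol synthesis without LPS 6 (0.190). Hypoxia and immediate early genes passed without untreated 1 (0.0137 and 0.0311).

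**Figure D2:**
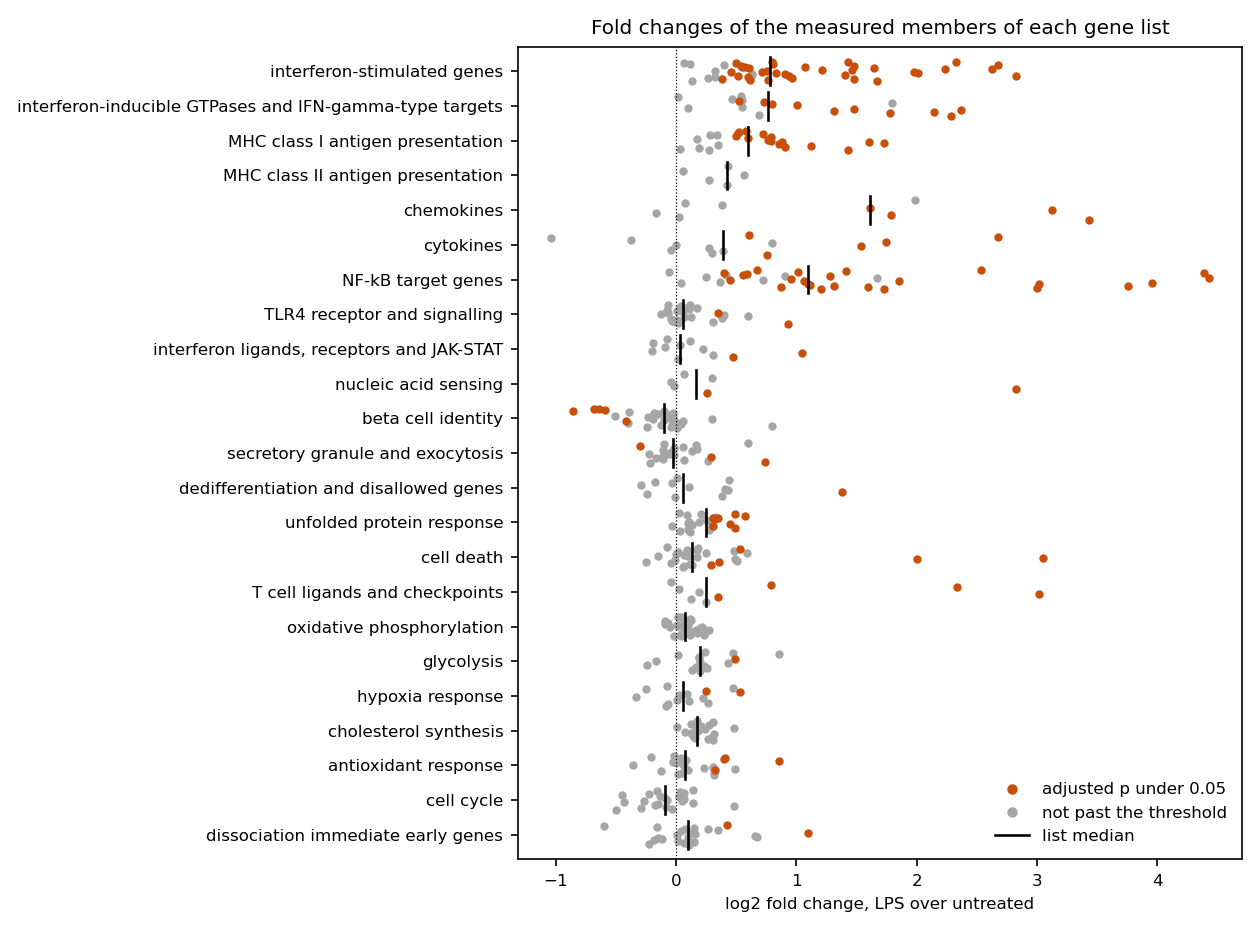
Log2 fold change, LPS over untreated (horizontal axis), of each measured member of 23 gene lists (n = 5 libraries per group); orange dots have an edgeR adjusted p under 0.05, grey dots do not, and black bars are list medians. In the interferon-stimulated list 35 of 44 members are called, in the NF-kB list 25 of 33 and in the MHC class I list 16 of 23, all above 0, while the 5 called beta cell identity genes lie below 0.

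Markers of other cell types were measured in the same libraries. Leukocyte transcripts were scarce: 3 of 22 macrophage markers and 2 of 18 lymphocyte markers passed the count filter, and neither list was called (camera adjusted p = 0.784 and 0.570). Cd68, a lysosomal protein gene, went from 16.8 ± 2.78 to 26.8 ± 4.78 CPM (SD, n = 5; edgeR adjusted p = 0.0141) but not past the threshold without untreated 3 (adjusted p = 0.0512). C1qa was at 18.7 ± 3.69 and 14.7 ± 1.85 CPM although the partner chain gene C1qb had 6 counts in all, and the macrophage list had a median of -0.20 and a mean of 0.04. The lymphocyte markers measured were Cd79a (2.67 and 1.93 CPM) and Lck (1.19 and 1.44 CPM), and Cd3e had 0 counts. Of the macrophage markers below the filter, Lyz2, Tyrobp and Csf1r had 14, 0 and 48 counts over the untreated and 4, 1 and 30 over the LPS libraries.

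Hormone genes of other islet cells were abundant, with Gcg at 8931 ± 3393 and 6558 ± 1834 CPM (SD, n = 5), Sst at 7068 ± 825 and 6637 ± 1572, Ppy at 1558 ± 465 and 783 ± 285 and Pyy at 849 ± 87.1 and 653 ± 178. Of these Ppy was called lower (log2 fold change -0.99, edgeR adjusted p = 0.0473; lost in 8 of the 10 leave-one-out fits, adjusted p up to 0.132), as was Frzb (-0.41) of the delta cell list, which was named after its value was seen. Pyy passed without LPS 8 (adjusted p = 0.0231). Cltrn (-0.20) and Rbp4 (-0.18), the next most abundant alpha and delta cell markers, did not pass. With the block for the title order, added after the data were seen, Gcg, Pyy and Cltrn were called lower (edgeR adjusted p = 0.00244, 0.00143 and 0.00776). Medians of the 11 alpha, 7 delta and 4 pancreatic polypeptide cell markers were -0.33, -0.18 and -0.51. These lists passed camera (adjusted p = 0.0153, 0.0232 and 0.0190), none of them with an estimated correlation (adjusted p = 0.607, 0.494 and 0.494). Pdx1 stands in both the delta and the beta cell list.

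Of 10 ductal markers, Spp1 (log2 fold change 0.97) and Muc1 (0.80), both named after their values were seen, rose, and 5 were higher when adjusted over the list alone. Krt8 (586 ± 89.8 and 777 ± 194 CPM; SD, n = 5) and Krt7 (424 ± 53.1 and 473 ± 53.8) were the most abundant and did not pass. In settings added after the data were seen, both were called higher with the block for the title order (edgeR adjusted p = 1.64e-04 and 0.0140). Krt8 also passed without the 4 libraries at the ends of the second principal component (adjusted p = 0.00659). The ductal list mean was 5.85 ± 0.0866 log2 CPM in untreated and 6.21 ± 0.189 in LPS libraries, apart in all (exact permutation p = 0.00794, the smallest this design can give; 0.0714 adjusted over 9 marker lists). The list passed camera (adjusted p = 0.00220) but not with an estimated correlation (adjusted p = 0.454). All 9 endothelial markers were lower in LPS, from -0.27 for Esam to -3.12 for Kdr, the only one called over all genes, against 8 when adjusted over the list alone, 0 in limma-voom and 0 to 7 in edgeR with single libraries left out. Eng, the second most abundant, was at 3.69 ± 2.93 and 0.915 ± 0.762 CPM. The endothelial list passed camera (adjusted p = 2.96e-04; adjusted p = 0.459 with an estimated correlation). Its mean of 1.04 ± 1.22 against -0.42 ± 0.75 log2 CPM did not pass the exact permutation test (p = 0.0635) with untreated 1, at -1.10, included and did without it (p = 0.00794). Acinar (19 measured) and mesenchymal (9 measured) markers held no called gene in edgeR, DESeq2 or limma-voom or when adjusted over the list alone. Each had 1 at an unadjusted p under 0.05 in edgeR (camera adjusted p = 0.184 for both, 0.0218 for both without untreated 5). Their most abundant members were Ctrb1 (0.14), Pnliprp1 (-0.06), Col1a1 (-1.05) and Col3a1 (-0.53), whose signs, like those of Eng and Sst, changed in some fits.

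**Figure D3:**
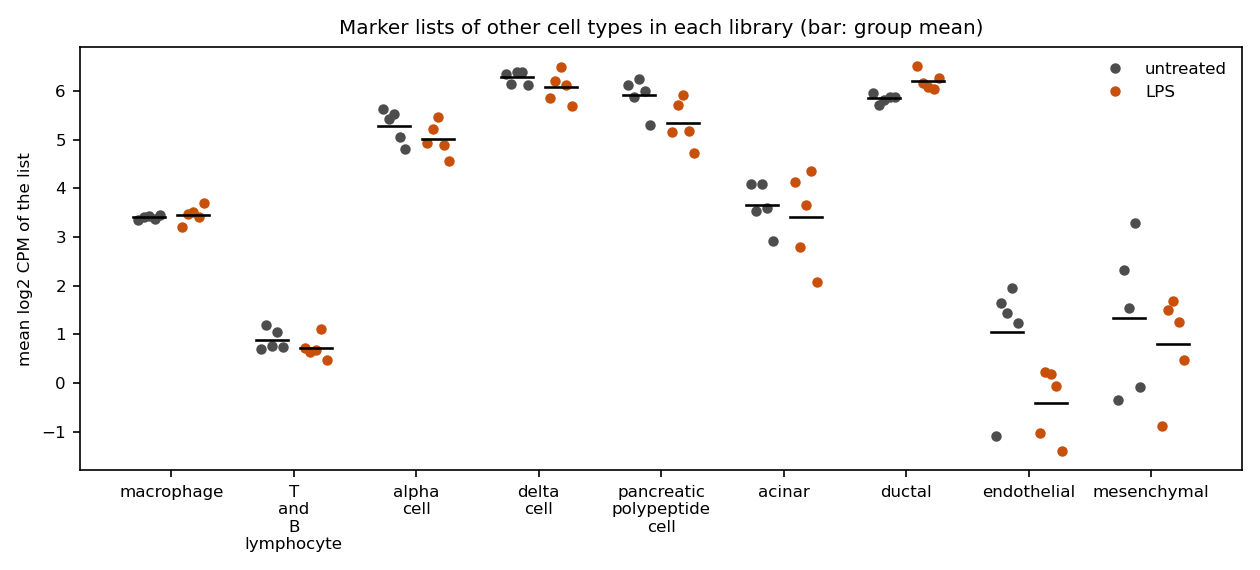
Mean log2 CPM of the measured members of 9 marker lists (vertical axis) in each untreated (grey) and LPS (orange) library, n = 5 each; bars are group means. Ductal means are higher in all LPS libraries (6.21 ± 0.189 against 5.85 ± 0.0866, SD), and endothelial means are higher in untreated libraries except untreated 1 (-1.10).

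Library composition was compared by exact permutation tests. Mitochondrially encoded genes took 2.53 ± 0.581% of counts in untreated and 2.11 ± 0.475% in LPS libraries (SD, n = 5; exact p = 0.214). Ins1 and Ins2 together took 10.6 ± 0.735% and 9.57 ± 1.22% (exact p = 0.119), and the 20 most abundant genes 20.1 ± 0.672% and 18.3 ± 1.29% (exact p = 0.0476, 0.238 adjusted over 5 planned measures). The insulin share differed without LPS 10 (exact p = 0.0159). Genes detected numbered 23177 ± 692 and 23447 ± 501 (exact p = 0.532). An abundant gene without a symbol, ENSMUSG00000119584, took 0.621 ± 0.211% and 0.320 ± 0.0726% of counts (exact p = 0.0159, 0.0794 adjusted over the unplanned measures) and was itself called lower (log2 fold change -0.96, edgeR adjusted p = 0.0234). With its share as a covariate 181 genes were called, and 201 with the endothelial list mean as a covariate, against 601 without, and 601 and 600 of the 601 kept their sign. The median size of their log2 fold changes was 0.62 (median SE 0.108) without a covariate, 0.62 (SE 0.159) with the unnamed gene and 0.53 (SE 0.133) with the endothelial covariate, so that larger errors, and in the latter fit also smaller fold changes, went with the lost calls. With the unnamed gene covariate 21 interferon-stimulated, 15 NF-kB target, 9 MHC class I and 2 unfolded protein response genes were called. In exact permutation tests neither quantity passed as different between the groups when adjusted (exact p = 0.0794 for the unnamed gene and 0.190 for the endothelial list). EdgeR nevertheless called the unnamed gene lower, and the endothelial list passed camera (adjusted p = 2.96e-04), so both covariates may overlap with the group. Both were added after the data were seen. The number of lower genes also depended on single libraries, with 75, 77, 89 and 76 called in place of 148 without untreated 2, untreated 3, untreated 4 and LPS 9.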

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

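The tests of this part were chosen after the results were seen, except the regrouping of the libraries and the test of GC content and transcript length, and those on macrophages and on ductal and beta cell shares replaced earlier versions whose outcome had been seen. Single libraries lay far from the other 4 of their group in 19 of 276 groups tested, where chance gives about 1 in 20 groups. LPS 6 stood apart most often: it was high for Ccl2 (3.86 CPM, others 1.16 to 1.77) and Lif (45.3, others 11.3 to 16.8). It was low for Plk5 (0.830, others 1.24 to 1.34), Mafa (896, others 1063 to 1131) and Pdx1 (109, others 132 to 141). Its list means were high for chemokines (3.28 log2 CPM, others 2.64 to 2.82) and cholesterol synthesis (6.75, others 6.02 to 6.19). Untreated 5 was high for Pdx1 (173 CPM, others 136 to 146), Cdk4 (184, others 147 to 152) and Krt7 (518, others 391 to 408). It was low for Lgals9 (1.77, others 4.43 to 5.05), Rbp4 (243, others 293 to 314) and the mean of the TLR4 signalling list (4.48 log2 CPM, others 4.67 to 4.74). In untreated 4, Vnn3 (0.775 CPM, others 0.203 to 0.296) and Icam1 (2.41, others 0.739 to 1.14) were high. Untreated 1 was low for the endothelial list mean (-1.10 log2 CPM, others 1.24 to 1.96) and high for glycolysis (6.34, others 5.84 to 5.93). The 2 remaining values were B2m in LPS 10 (455 CPM, others 377 to 385) and Slc6a14 in untreated 2 (0.324 CPM, others 0 to 0.0821).

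Of 100 splits of the 10 libraries into groups of 5, 1 gave as many called genes as the split by treatment, namely that split itself with 601. The highest of the others gave 1. A share of 1 of 100 is the smallest these splits can give, so chance is unlikely for this count but not excluded. The others mixed libraries of both treatments in each group, so a difference by treatment would have widened the spread within their groups.

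Interferon-stimulated and NF-kB target genes rose together, 60 called members of both lists with a median log2 fold change of 1.10. Low counts of most macrophage markers argue against macrophages left in the sort as the source of the whole rise. Of 22 markers, 19 lay under 10% of the median rise of 15.9 CPM. Among them Lyz2, Tyrobp and Csf1r had 4, 1 and 30 counts over the LPS libraries. The median of all 22 was at most 0.124 CPM in an LPS library, 0.781% of that rise, but adds no separate test. Its outcome was fixed, since 19 markers were known to lie below the count filter when it was chosen. Cd68 and C1qa, above the filter, leave it undecided whether macrophages gave a part of the rise. A larger share of ductal cells cannot be told apart from a rise within the sorted cells, because the 5 ductal markers under 100 CPM had a median of 0.75, with upper 95% limits of 1.30 for Krt19 and Spp1 above the median of the called genes, although Sox9 (0.01) stayed near 0. Earlier versions gave a macrophage marker sum of 1.73% of the summed rise, mostly Cd68 and C1qa and undecided at bounds of 1% and 10%, 0.0374% for the 19 markers below the count filter, which fixed that outcome, and an upper limit of 1.30 for Krt19 against a smallest value of 3.69 among the 10 largest increases, which cannot speak for the whole set. The exposure to LPS, acting on the sorted cells or through other islet cells, stays open as the biological explanation, and no library separates the direct from the indirect route.

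Of 30 beta cell identity genes, 5 were called lower, with a median of -0.64. Of the members not called, 19 lay under 0 and 6 above. The list mean was 8.61 ± 0.0645 log2 CPM in untreated and 8.44 ± 0.0473 in LPS libraries (SD, n = 5). These means were apart in all libraries (exact permutation p = 0.00794, 0.0166 adjusted over 23 lists). A lower share of beta cells would raise markers of the cells that took their place. The medians of alpha (-0.33), delta (-0.18) and pancreatic polypeptide cell (-0.51) markers lay under 0, while that of ductal markers was 0.29. The median of all 30 beta cell members was -0.10 (median absolute deviation 0.163). Its gap to -0.64 cannot exclude a change in shares, because the 5 members were called for their fall. A lower share would also not move all members alike where other islet cells express them, as with Pdx1, which stands in the delta list too. Ins1 (-0.10) and Ins2 (-0.19) fell by less than the 5 called members. A larger share of ductal cells stays open. The earlier version on the 25 members not called, a choice that leaves out the genes in question, gave a median of -0.07. Removing the trend of fold change on GC content and transcript length, which moved tested genes by a median of 0.0390, left the 5 called members at -0.69. A lowering of these transcripts in LPS-exposed beta cells may be followed up as a hypothesis, found and tested on the same libraries. A change in cell shares stays open beside it.

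Libraries of both groups also spread along the second principal component, which held 18.9% of the variance, and fell along it in the order of their title numbers, from 24.5 to -24.2 in untreated 1 to 5 and from 28.2 to -36.3 in LPS 6 to 10. Its position correlated with the mitochondrial share of counts (Spearman's rho -0.745, permutation p = 0.0172, adjusted over 4 relations 0.0467; Pearson's r -0.778, permutation p = 0.00874, adjusted 0.0175; r -0.857 without the 2 most extreme libraries). It also correlated with the share of Gcg (rho 0.721, permutation p = 0.0233, adjusted 0.0467; r 0.777, permutation p = 0.00755, adjusted 0.0175; r 0.633 without the extremes). The relation with library size was not decided (rho 0.261, permutation p = 0.469; r 0.0702, permutation p = 0.849; r -0.178 without the extremes), and the acinar list mean gave rho 0.382 (permutation p = 0.279, adjusted 0.372) and r 0.654 (permutation p = 0.0401, adjusted 0.0534; r 0.516 without the extremes). Differences in RNA quality or in alpha cell carry-over may each contribute, though both shares enter the component themselves, while an order of processing or islet batches shared across the groups, which the labels do not give, stays open, and no biological explanation was tested.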

How the results depend on the processing

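The covariates other than the surrogate variable, the acinar and the macrophage list means, the fit without the 4 libraries at the ends of the second principal component (untreated 1, untreated 5, LPS 6 and LPS 10), and the block for the order of the title numbers were chosen after the results were seen. The count of 601 called genes (453 higher, 148 lower) ran from 571 to 745 under other scalings, filters, thinning, limma-voom and the acinar, macrophage and alpha cell covariates or without the 4 libraries. It ran from 401 to 624 when each library was left out (higher genes 324 to 458, lower genes 75 to 166, under 99 without untreated 2, untreated 3, untreated 4 or LPS 9, at 75, 77, 89 and 76). It was 949 (657 higher, 292 lower) with DESeq2, 994 (693 and 301) with limma-voom and quality weights and 1335 (864 and 471) with 1 surrogate variable. It was 1311 (847 and 464) with the second principal component, 201 (183 and 18) with the endothelial list mean and 181 (159 and 22) with the share of ENSMUSG00000119584. All 601 calls were among those with the surrogate variable and with the component, which correlated at r = -0.987, and 599 among those of DESeq2, but 198 and 174 under the last 2 covariates. Higher genes made up 75.4% of calls, 64.7% with the surrogate variable, 64.6% with the component, 54.5% with the block for the order of the title numbers, 91.0% with the endothelial and 87.8% with the unnamed gene covariate. Of 71 named genes called, 62 stayed called under all planned settings other than leaving out a library and 54 in all 10 leave-one-out fits, and 31 and 37 were lost with the endothelial and the unnamed gene covariate. Cxcl10 stayed called in all fits (1.15 to 1.77) except with the unnamed gene covariate (1.40, adjusted p = 0.161; 4.94e-10 to 0.00590 over planned settings). Ifngr1 was called with the surrogate variable, the component and the macrophage covariate, and Pdx1 with the first 2 of these. Genes that were not called changed sign as follows, given as log2 fold changes: Tlr4 -0.34 (endothelial), -0.0574 (without the 4 libraries) and -0.12 to 0.43 (each library left out); Ifnar1 -0.0273 (without the 4) and -0.0333 to 0.0414 (each left out); H2-DMa -0.0002408 (acinar), -0.0644 (alpha cell) and -0.0276 to 0.19 (each left out). Atp5a1 reached 0.007914 (alpha cell) and -0.0464 to 0.004339 with each library left out, Cdk4 -0.0207 (alpha cell) and -0.00716 to 0.11, and Sst 0.0750 (alpha cell), 0.0873 (without the 4) and -0.21 to 0.008294. Ctrb1 was at -0.0109 (limma-voom), -0.00258 (block) and -0.13 to 0.34, Eng at 0.89 (endothelial) and Col1a1 at 0.89 (endothelial) and 0.0272 (unnamed gene). Pnliprp1 was at 0.0394 (surrogate variable), 0.0647 (acinar), 0.14 (macrophage), 0.0588 (component), 0.34 (alpha cell), 0.0909 (unnamed gene) and -0.32 to 0.20, and Col3a1 at 0.40 (limma-voom), 0.23 (with quality weights), 1.77 (endothelial), 1.05 (unnamed gene), 0.0339 (block) and -0.82 to 0.45. With an estimated correlation the list calls were lost for TLR4 signalling (adjusted p = 0.267), nucleic acid sensing (0.177), beta cell identity (0.0655), cell death (0.0572), oxidative phosphorylation (0.421), glycolysis (0.396), cholesterol synthesis (0.427) and antioxidant response (0.267). With fry they were lost for TLR4 signalling (0.0660), oxidative phosphorylation (0.197), glycolysis (0.160) and cholesterol synthesis (0.259). Among marker lists, alpha (0.607), delta (0.494), pancreatic polypeptide (0.494), ductal (0.454) and endothelial (0.459) calls were lost with an estimated correlation. Leaving out each library moved camera's adjusted p from 4.62e-04 to 0.258 for MHC class II (past the threshold without untreated 3 or 4), 0.0138 to 0.190 for TLR4 signalling (lost without untreated 5, LPS 6 or LPS 7) and 0.00430 to 0.0553 for nucleic acid sensing (lost without untreated 5 or LPS 7). The range was 7.96e-04 to 0.112 for oxidative phosphorylation (lost without LPS 10) and 5.48e-05 to 0.190 for cholesterol synthesis (lost without LPS 6). It moved dedifferentiation genes from 0.0363 to 0.350 (past without untreated 1 or LPS 10), hypoxia from 0.0137 to 0.195 and immediate early genes from 0.0311 to 0.888 (past without untreated 1). It turned the direction of secretory granules (0.534 to 0.978, without untreated 5 or LPS 6) and of acinar markers (0.00766 to 0.903, without LPS 10). Of the acinar and mesenchymal lists, the former passed without untreated 5 or LPS 9 and the latter without untreated 1 or untreated 5. The difference in genes detected, 270, ran from -12.25 to 421.8. The cause was not tested for these changes, except that fewer libraries were fitted where some were left out. Called interferon-stimulated genes numbered 31 to 35, interferon-inducible GTPases 7 to 11, NF-kB targets 22 to 25, MHC class I genes 15 to 18, unfolded protein response genes 7 to 9 and lower beta cell identity genes 5 to 7 over the leave-one-out fits. Cytokines numbered 3 to 6, antioxidant genes 2 to 5, TLR4 signalling and glycolysis genes 0 to 2, higher granule genes 1 to 3 and lower endothelial markers 0 to 7. With the endothelial and the unnamed gene covariate the called members numbered 26 and 21 for interferon-stimulated genes, 7 and 5 for the GTPases, 17 and 15 for NF-kB targets, 12 and 9 for MHC class I and 5 and 2 for the unfolded protein response. They numbered 3 and 2 for chemokines, 1 and 2 for cytokines, 4 and 1 for cell death and 3 and 5 for lower beta cell identity genes, and 0 under both for TLR4 signalling, interferon ligands and receptors, and antioxidant genes. Depth limits what can be said of Cxcl9, Ccl20, Ifnb1 and the leukocyte markers, most of which had too few counts to be tested. From the labels, no paired analysis was possible because the replicate numbers of the groups, 1 to 5 and 6 to 10, have none in common. A block that assumes pairs by the order of the title numbers, untreated 1 with LPS 6 up to untreated 5 with LPS 10, called 2450 genes (1336 higher, 1114 lower), all 601 among them. Libraries at the same place in the order deviated from their group means with correlations of 0.485, 0.210, 0.213, 0.0802 and 0.421, a mean no other of the 120 pairings of the groups reached. Not every library correlated best with its own partner (untreated 4 did with LPS 7), and this is a hint from the data, not the design. Under the block Ifngr1, Krt8 and Krt7 were called higher and Ins2, Mafa, Pdx1, Ccnd2, C1qa, Gcg, Cltrn, Pyy and Eng lower, as were 13 beta cell identity genes in place of 5, and no named call was lost. It also called 7 genes each of oxidative phosphorylation and cholesterol synthesis higher and 4 of cell cycle lower.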

Other observations

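The genes of this part were chosen after their values were seen, and all tests on them are those of the edgeR fit. In the LPS libraries the fibrinogen chain genes Fga (1.16 ± 0.694 to 14.95 ± 5.40 CPM, SD, n = 5; log2 fold change 3.68, edgeR adjusted p at most 0.00144 for the chains), Fgb (1.91) and Fgg (2.49) rose together. So did Orm1 (5.29), a plasma glycoprotein gene, Hamp (1.89), the gene of the iron hormone hepcidin, and Serpina3n (1.83), which belongs to a family of similar copies. By its fold change Orm1 would have stood among the largest increases ranked above, but it did not meet that ranking's limits on level and separation. The complement genes C3 (6.85 ± 2.51 to 54.8 ± 18.2 CPM; 3.00), C1ra (2.05) and the C1 inhibitor gene Serping1 (1.05) rose as well. Acod1, whose product makes itaconate in activated macrophages, went from 0.0238 ± 0.0350 to 1.42 ± 0.368 CPM (5.57), at few counts per library. Pigr (1.49), the receptor that carries IgA across epithelia, and the membrane mucin gene Muc13 (1.97) rose too, the former with overlapping groups.

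The neuropeptide genes Gal (log2 fold change 2.32) and Nts (1.89) rose, as did the opioid precursor gene Pdyn (122 ± 26.1 to 218 ± 12.9 CPM, SD, n = 5; 0.84, edgeR adjusted p = 0.00141). Among the decreases were those of the GABA synthesis enzyme gene Gad1 (92.0 ± 17.1 to 63.4 ± 6.58 CPM; -0.54), the glutamate receptor gene Gria2 (-0.68, with overlapping groups), the cannabinoid receptor gene Cnr1 (-0.71) and the exocytosis regulator gene Cplx2 (-0.46). Of metabolic genes, Hadh (388 ± 22.6 to 302 ± 17.9 CPM; -0.36), whose loss causes excess insulin secretion in humans, and Gpd2 (-0.40), of the glycerol phosphate shuttle, fell. Ngfr (-1.87) and Lars2 (497 ± 163 to 268 ± 52.4 CPM; -0.89) fell with overlapping groups.

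The endothelial list mean per library was -1.10, 1.64, 1.45, 1.96 and 1.24 log2 CPM in untreated 1 to 5 and -1.03, 0.23, 0.18, -0.07 and -1.40 in LPS 6 to 10. All 9 measured members had fold changes under 0, and the exact permutation test of the means gave p = 0.0635, or 0.00794 without untreated 1. An explanation by endothelial carry-over was tried on these values and left undecided.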
